A study of Mus musculus with 3 samples.

How the data were processed

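Bulk RNA sequencing data were used from 3 libraries of sorted mouse mammary cells, 1 library for each of 3 populations. The labels give them as epithelial cells positive for PROCR, the protein C receptor. Per the labels, all 3 populations came from a gate of EpCAM-positive cells with high CD49f, the integrin alpha 6 chain, and were divided by the surface proteins CD36 and podoplanin (PDPN). They are called the CD36+ library (CD36 positive, PDPN negative), the PDPN+ library (CD36 negative, PDPN positive) and the double-negative library (negative for both). The sample titles give the CD36+ and double-negative populations as Cdh5 positive and the PDPN+ population as Cdh5 negative. Groups were taken from these labels. How many mice or cells stood behind each library is not given in the sources used here. The design text of the series also speaks of single-cell sequencing, which was not analysed here.

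Per the labels' protocols, total RNA was isolated with either of 2 extraction kits. Samples with little RNA went through a low-input single-cell kit, and samples with ample RNA through a stranded kit that removes ribosomal RNA. Both the NextSeq and the NovaSeq instruments were used for sequencing. Which kit and instrument served which library is not given in the sources used here, so neither can be set against the populations, and a difference in library chemistry between populations is not excluded in any comparison. Without molecular identifiers, reads may be PCR copies of the same molecule.

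The authors deposited 1 gene table per library, with estimated counts per gene, which need not be whole, and with TPM, a share of transcripts corrected for transcript length. Per the submitters' processing notes, Salmon 0.9.1 and the mm10 build were used. The file headers give effective gene lengths beside the values. The annotation release, the strand setting and any read filter are not given in the sources used here. Each table held 52661 gene identifiers.

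The deposited estimated counts were rounded to whole numbers before use. Gene symbols, biotypes and coordinates were taken from GENCODE M21, which uses the mm10 sequence. With the version suffix, 50410 identifiers matched it, and 52566 matched without the suffix. Genes without a match held at most 0.00987% of the counts of a library. Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed over all 3 libraries. Levels are in CPM after TMM scaling. Log2 ratios used a prior count of 2. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

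No group had a replicate, so no test between populations was possible and no p-value is given. Differences between libraries compare those libraries, not the populations. A gene was counted as apart where its ratio was at least 4-fold and the higher library held at least 10 CPM. Folds of named genes carry exact (Clopper-Pearson) 95% intervals from the counts. These intervals and the floors cover counting error only. A fold against a library with 0 counts was computed against a floor of 3 counts in that library and is given as "at least". A floor of 3 counts corresponded to 0.0507 CPM in the CD36+ library, 0.0406 CPM in the PDPN+ library and 0.0594 CPM in the double-negative library.

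Named genes came mainly from a set given by a fixed rule, and not every gene of the set is named, since some are not reported here. The rule took the 8 genes of the sort and the titles, the 10 nuclear protein-coding genes with the largest ratio in each direction of each comparison (at least 20 CPM in the higher library, predicted and ribosomal protein genes left out), the ID and E protein genes, and up to 4 members per gene list with the highest mean level. List members at least 4-fold apart against the direction of their list were also taken. Genes outside this rule were chosen after their values were seen. These are the most abundant genes of a library, further list members given as examples, such as Ptprc, Prox1 and Cited1, the 11 abundant genes apart between the CD36+ and double-negative libraries, and the genes of the closing observations other than the 6 of high endothelial venules.

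There were 30 gene lists. They covered the sort and title genes, endothelial types (all, capillary, lymphatic, venous, arterial), epithelial types (basal, myoepithelial, luminal, alveolar, hormone-sensing, junction), other cell types (fibroblast, pericyte, immune, adipocyte, Schwann, erythroid), mammary stem cell, ID and E protein, mesenchymal transition, Notch, Wnt, BMP and TGF-beta, fatty acid, basement membrane, cell cycle, dissociation stress and interferon genes, and RNAs without a poly(A) tail. Members with at least 1 CPM in any library were measured. Each list has its median log2 ratio, its number of members at least 2-fold higher or lower, and the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Intervals of list medians came from 2000 bootstrap draws of the members. Where members with no counts in a library moved a median by more than 0.05, the median with those members at their bound is also given. Some lists share genes, such as Fabp4 and Gpihbp1 in the capillary and fatty acid lists. A further 5 short lists, used only in the closing observations, were written after the data had been opened. For 1 of them, the 6 genes of high endothelial venules, the values of its members had not been seen, and for the others they had been seen in part.

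The grouping, the size rule, the naming rule, the 30 lists and the alternative settings were set before the data were examined. The alternatives were DESeq2 1.42.0 size factors, total counts, upper quartile scaling, other minimum levels, prior counts and fold thresholds, the deposited TPM, the nearer bound of the counting interval, removal of the most abundant genes, thinning to the smallest library and a higher minimum for list members. A minimum mean level of 160 CPM was added after the data were seen.

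The calculations were tested on simulated data, with Poisson counts drawn for the 52661 genes of each comparison. In each of the 3 comparisons, 100 of 100 genes changed 8-fold were recovered and 0 unchanged or 2-fold genes were counted. The 95% intervals held the true ratio for 94.9% of the genes with CD36+ against PDPN+, 95.6% with CD36+ against double-negative and 94.9% with double-negative against PDPN+. The simulation held counting error only, and no variation between animals or libraries.

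Reads shared by near-identical genes make values uncertain for Tgtp2, Gbp2b, Ccl21a, Serpina1b, Pcdhb9, the hemoglobin genes, the histone genes and the H2 genes. Because the strand setting is not known, reads of overlapping or antisense genes may not have been told apart.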

Results

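Gene expression was measured by bulk RNA sequencing in 3 sorted mouse mammary populations that the labels give as PROCR-positive epithelial cells. There was 1 library for each population, so no value has a replicate error. Total estimated counts were 67675778 in the CD36+ library, 63871266 in the PDPN+ library and 51138993 in the double-negative library. Reads were found for 26028, 27636 and 27973 genes in the same order, and 7437, 7872 and 7543 genes reached 10 CPM. Mitochondrially encoded genes took 2.08%, 2.07% and 2.11% of the counts. The 50 most abundant genes of each library took 21.8%, 15.1% and 20.3%. Across 10223 genes with at least 10 CPM in any library, the correlation of log2 levels was highest between the CD36+ and double-negative libraries (Pearson 0.605, Spearman 0.759). It was 0.417 and 0.585 between the CD36+ and PDPN+ libraries, and 0.391 and 0.579 between the double-negative and PDPN+ libraries. These correlations are across genes, which are not independent replicates.

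The most abundant nuclear coding transcript of the CD36+ and double-negative libraries was Ackr1, an atypical chemokine receptor of venular endothelium, at 18761 and 17174 CPM. Selp, the adhesion molecule P-selectin, was second, at 15929 and 9067 CPM. In the PDPN+ library the most abundant were the histone gene H3f3b at 6028 CPM and the clock-related repressor Bhlhe41 at 5572 CPM, and Sfn, an epithelial 14-3-3 protein, stood at 2108 CPM.

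The genes of the sort and of the titles were examined first, since the study asked about differentiation of mammary epithelial stem cells and its title names TCF4 and ID3. Tcf4, which encodes an E protein transcription factor (chromosome 18, 69343356 to 69689079, plus strand of mm10), stood at 1190.5 CPM in the CD36+ library, 1174 in the double-negative library and 23.6 in the PDPN+ library. It was 50.5-fold higher in the CD36+ than in the PDPN+ library (95% counting interval 48.1 to 52.9) and 49.7-fold higher in the double-negative library (47.4 to 52.2). Between the CD36+ and double-negative libraries Tcf4 was 1.01-fold apart, with a direction that turned under scaling by total counts. By the deposited TPM, Tcf4 stood at 479, 23.4 and 633 in the CD36+, PDPN+ and double-negative libraries. Both Tcf4 folds against the PDPN+ library were smaller by TPM and lay below the counting intervals given here. The TPM of Tcf4 was higher in the double-negative than in the CD36+ library. Id3, which encodes an inhibitor of E proteins (chromosome 4, 136143497 to 136145755, plus strand), stood at 57.6, 60.6 and 53.5 CPM in the CD36+, PDPN+ and double-negative libraries. With TMM scaling no pair differed by more than 1.13-fold, and every Id3 direction turned under total counts or upper quartile scaling. By the deposited TPM, Id3 stood at 58.2, 85.7 and 69.7 in the same order, and every gap was wider.

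Cdh5, the endothelial cadherin (chromosome 8, 104101625 to 104144511, plus strand), stood at 465 CPM in the CD36+ library, 206 in the double-negative library and 0.176 in the PDPN+ library. It was 2.26-fold higher in the CD36+ than in the double-negative library (2.21 to 2.31). Cd36, a fatty acid receptor (chromosome 5, 17781690 to 17888801, minus strand), stood at 4766 CPM in the CD36+ library, 45.1 in the PDPN+ library and 1523 in the double-negative library, which had been sorted as CD36 negative. Cd36 was 3.13-fold higher in the CD36+ than in the double-negative library (3.10 to 3.15), and 33.8-fold higher in the double-negative than in the PDPN+ library (32.6 to 35.0). Pdpn (chromosome 4, 143267431 to 143299564, minus strand) stood at 830.2 CPM in the PDPN+ library, 32.3 in the double-negative library and 12.5 in the CD36+ library. Procr (chromosome 2, 155751117 to 155755471, plus strand) stood at 746, 208 and 528 CPM in the CD36+, PDPN+ and double-negative libraries. Epcam, the epithelial adhesion gene used in the gate (chromosome 17, 87635979 to 87651129, plus strand), stood at 560.1 CPM in the PDPN+ library. It was lower in the CD36+ library (50.7 CPM, interval of the fold 10.6 to 11.5) and 5.41-fold lower in the double-negative library (104 CPM, 5.25 to 5.56). Itga6, which encodes CD49f (chromosome 2, 71745616 to 71858416, plus strand), stood at 436, 1021 and 399 CPM in the CD36+, PDPN+ and double-negative libraries, and its 1.09-fold gap between the first and the last turned direction under total counts.

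**Figure D1:**
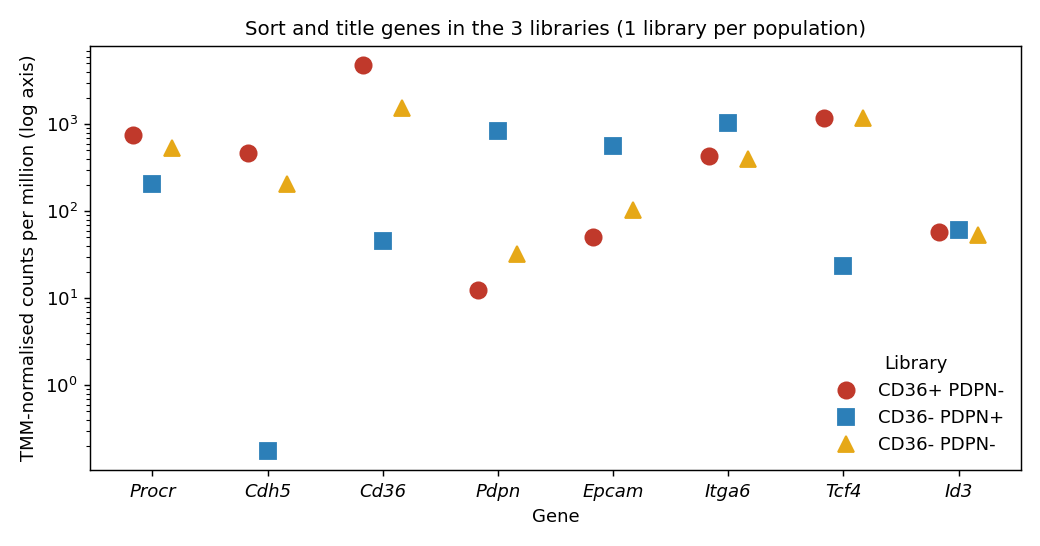
TMM-normalised CPM (log axis) of the 8 sort and title genes, with 1 point per library and no error bars, since each population had 1 library. Tcf4 sits at 1190.5 and 1174 in the CD36+ and double-negative libraries and at 23.6 in the PDPN+ library, and Id3 between 53.5 and 60.6 in all 3.

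The CD36+ and PDPN+ populations differ in both surface proteins and in the Cdh5 state given in the titles. In the CD36+ library, genes of endothelial cells were higher, and genes of basal and myoepithelial cells were lower. Of 20 measured pan-endothelial genes, 19 were at least 4-fold higher in the CD36+ library, with a median log2 ratio of 5.96, and Sox18 was within 2-fold. Of 12 measured basal epithelial genes, 10 were at least 4-fold lower, with a median of -5.37, and Tspan8 went the other way. At the size rule, 1415 genes were higher and 1654 lower in the CD36+ library, of 9387 with at least 10 CPM in either library. Under total-count scaling, which moved every log2 ratio of this pair by -0.40, the numbers were 1120 and 2124. Upper quartile scaling moved the ratios by 0.27 and turned the balance, with 1660.0 higher and 1381 lower. Among the 1277 genes with a mean of at least 160 CPM, a minimum added after seeing the data, 192 were higher and 62 lower.

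Among the pan-endothelial genes, Pecam1, an adhesion molecule of endothelial junctions, stood at 1475 CPM in the CD36+ library and 68.4 in the PDPN+ library, a ratio of 21.6 (21.0 to 22.2). Emcn, Cd93 and Flt1, a VEGF receptor, were 40.4-fold, 55.7-fold and 61.0-fold higher. All 7 venous genes were measured, and 6 were at least 2-fold higher (median 5.18). Ackr1 was 146-fold higher (143 to 149), Selp 91.7-fold, Lrg1 36.2-fold and Sele 34.2-fold. Of 11 capillary genes, 10 were at least 2-fold higher (median 6.83), among them the fatty acid binding protein Fabp4, 114-fold (109.9 to 118), the water channel Aqp1, 67.7-fold, Cav1, 4.50-fold, and Cdh13, 3.11-fold. Each of these 3 medians lay above those of all 10000 random lists. Of 9 arterial genes, 7 were at least 2-fold higher (median 4.30), among them Fbln5 (3.24-fold), Sox17 (19.9-fold) and Efnb2 (3.67-fold). Cxcl12 and Hey1 went the other way, Cxcl12 at 33.4 against 134 CPM and Hey1 at 0 against 20.9 CPM.

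Of the basal genes, Trp63, the transcription factor of basal epithelium, had 3 counts in the CD36+ library and 1753 CPM in the PDPN+ library. The basal keratin Krt14 stood at 0.186 against 1425 CPM, Krt17 at 3.35 against 1045 CPM (312-fold, 272 to 361) and the laminin chain Lama3 at 6.93 against 297 CPM. Tspan8 stood at 128 CPM in the CD36+ library and 0.0270 in the PDPN+ library. Of 12 myoepithelial contractile genes, 11 were at least 2-fold lower in the CD36+ library (median -4.32), among them the smooth muscle actin Acta2 (22.4-fold lower, 21.5 to 23.4), Myh11 (17.7-fold) and Mylk (4.52-fold). Tpm2, a tropomyosin of this list, had 2 counts in the CD36+ library and 399 CPM in the PDPN+ library. Of 11 epithelial junction genes, 7 were at least 2-fold lower (median -2.49). The epithelial cadherin Cdh1 was 249-fold lower (189.7 to 335), the desmosomal genes Dsp and Dsg2 were 5.60-fold and 3.93-fold lower, and Jup was 6.72-fold lower. Cldn3 and Cldn7 were among those that went the other way, at 7.67 and 5.29 CPM in the CD36+ library.

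Of 11 measured genes linked to mammary stem cells, 6 were at least 4-fold lower in the CD36+ library and 3 at least 4-fold higher, with a median of -4.07. Sox9 was 29.4-fold lower (28.0 to 30.8), at 29.9 against 879 CPM. Id4 stood at 0.118 against 352 CPM. Foxp1 was 1.33-fold lower. Zeb1, a repressor of epithelial genes, was 179-fold higher in the CD36+ library (151 to 215), and Inpp5d and Cdh4 were the other members that went that way. Of 14 Wnt genes, 9 were at least 2-fold lower (median -3.84), among them Lgr4, at 12.9 against 215 CPM. Tcf7l2 and Fzd4, a frizzled receptor, were 2.65-fold and 20.3-fold higher, and Znrf3 was 1.34-fold lower. Of 9 ID and E protein genes, 5 were at least 2-fold lower and 3 at least 2-fold higher (median -1.14), the latter being Tcf4, Id1 and Tal1. Tcf12 was 2.20-fold lower and Id2 2.91-fold lower in the CD36+ library. Tcf3 stood at 0.338 against 10.1 CPM. Id1 stood at 9.54 CPM in the CD36+ library and had 0 counts in the PDPN+ library, a ratio of at least 235.

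Interferon-response genes were also higher in the CD36+ library, with 8 of 10 at least 4-fold higher (median 4.46, above all random lists), among them Rtp4, Bst2 (40.8-fold) and Rsad2 (447-fold, 292 to 723). Isg15 stood at 55.9 against 4.64 CPM. Of 11 alveolar luminal genes, 9 were at least 2-fold higher (median 4.14). The most abundant was Cd14, a coreceptor for bacterial lipopolysaccharide that myeloid cells also carry, at 929 against 15.2 CPM. Kit, a receptor tyrosine kinase, stood at 129.95 against 7.36 CPM and Wfdc18 at 60.6 against 22.9 CPM, while Mfge8 was 1.75-fold lower. Of 12 basement membrane genes, 7 were at least 2-fold higher (median 1.56), among them Nid1 (3.87-fold) and Col4a1 (3.46-fold), while Sparc and Lamc1 were 1.37-fold and 1.73-fold higher. Lama1 went the other way, with 1 count in the CD36+ library. Of 15 dissociation stress genes, which respond to tissue digestion, 11 were at least 2-fold higher in the CD36+ library (median 1.60), among them Ier3 (5.17-fold) and Hspa1a (5.59-fold), while Dusp1 and Ier2 were 1.65-fold and 1.22-fold higher.

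The largest ratios towards the CD36+ library were those of the interferon-induced GTPase genes Tgtp2, Gbp2b and Gbp3, followed by St3gal6, Mctp1, Rtp4, Egfl7, Esam, Tek and Asb4. Tgtp2 stood at 1127 CPM against 0 counts, a ratio of at least 27782. Gbp3, St3gal6, Mctp1, Rtp4 and Asb4 also had 0 counts in the PDPN+ library, with ratios of at least 8465, 7597, 7469, 5761 and 3909. Gbp2b, Egfl7, Esam and the angiopoietin receptor gene Tek had 1 count there, against 670.4, 328, 282 and 274 CPM. Among the largest ratios towards the PDPN+ library were those of Trp63, Serpinb5, Cxcl13, Krt14, Tpm2, Fermt1, Perp, Rerg and C9orf72. Serpinb5, the desmosomal gene Perp and Rerg had 0 counts in the CD36+ library, with ratios of at least 7041, 3129.6 and 3037. The B cell chemokine Cxcl13 had 3 counts against 588 CPM. Fermt1, a kindlin of epithelial adhesion, had 2 counts against 391 CPM, and C9orf72 had 1 count against 224 CPM.

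The other lists of this comparison divided as follows. Of 12 fibroblast genes, 10 were at least 2-fold lower in the CD36+ library (median -2.84), among them the proteoglycan gene Dcn, at 43.1 against 423 CPM. Lum and Col3a1 stood at 49.0 against 51.1 and at 8.46 against 51.8 CPM, and Fbn1 went the other way, 4.33-fold higher. Of 10 Notch genes, 4 were higher and 5 lower (median -0.76), with the ligand Jag1 5.50-fold lower, Dll1 at 113.5 against 75.8 CPM and the receptor Notch1 47.7-fold higher. Of 17 BMP and TGF-beta genes, 7 were higher and 5 lower (median 0.73), with Tgfbr3 and Bmpr2 at 1446 and 1329.97 CPM in the CD36+ library against 744 and 399.8 CPM. Of 13 fatty acid genes, 7 were higher and 0 lower (median 1.82). Of 11 luminal genes, 4 were higher and 6 lower (median -1.12), with the keratins Krt18 and Krt8 2.17-fold and 2.66-fold lower. Of 10 cell cycle genes, 6 were higher and 1 lower (median 1.78), among them Pcna (2.86-fold) and Tyms (16.1-fold). Of 10 mesenchymal transition genes, 3 were higher and 6 lower (median -2.17), with Vim 6.18-fold higher and Snai2 at 0.0676 against 104 CPM. These counts are of members at least 2-fold apart.

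Since each population had 1 library, none of these differences has a replicate check. Folds of genes below 1 CPM in the lower library rest on few counts or none there.

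**Figure D2:**
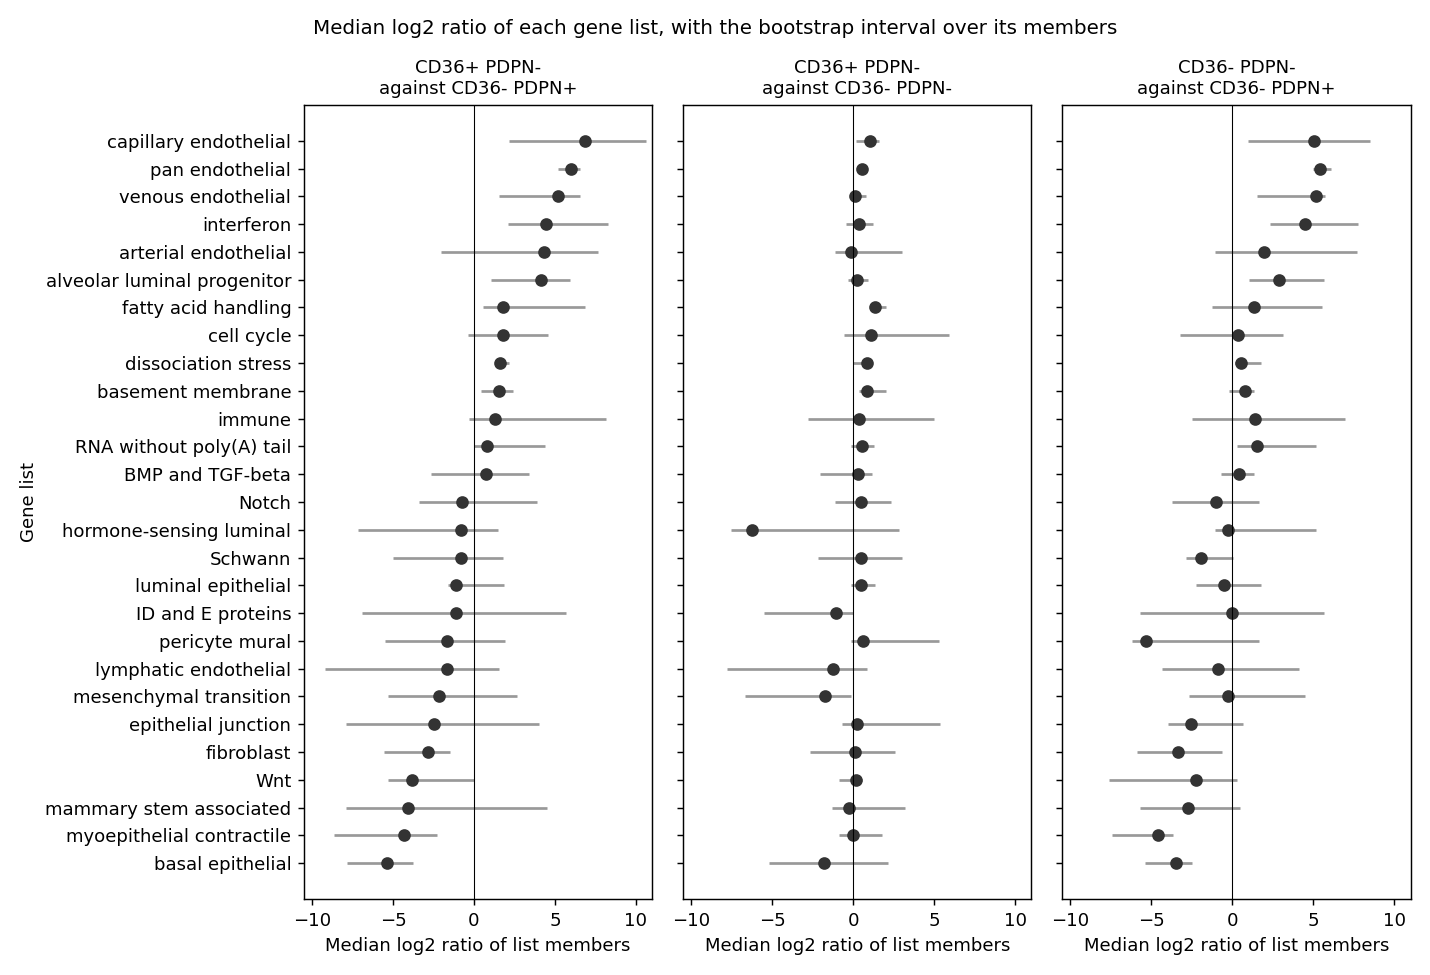
Median log2 ratio of the measured members of the gene lists in the 3 comparisons, with lines for the bootstrap interval over the members. The sort and title, erythroid and adipocyte lists are not drawn. Positive values mean higher in the library named first. Pan-endothelial genes sit at 5.96 and 5.44 against the PDPN+ library and at 0.57 between the CD36+ and double-negative libraries, and basal epithelial genes at -5.37, -3.48 and -1.78.

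The double-negative and PDPN+ populations differ in PDPN and in the Cdh5 state of the titles, and both were sorted as CD36 negative. This comparison and the previous one share the PDPN+ library, so they are not independent of each other. In the double-negative library, 19 of 20 pan-endothelial genes were at least 4-fold higher (median 5.44), and 11 of 12 basal genes were at least 2-fold lower (median -3.48), with Tspan8 going the other way at 39.7 against 0.0270 CPM. At the size rule, 1422 genes were higher and 1834 lower in the double-negative library, of 9515. With a mean of at least 160 CPM the numbers were 155 and 63 of 1220. Total counts moved the log2 ratios of this pair by -0.23, with 1282 higher and 2163 lower. Upper quartile scaling moved them by 0.28 and turned the balance, with 1689 higher and 1530.0 lower.

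Pecam1 was 17.0-fold higher in the double-negative library (16.5 to 17.5), Emcn 32.9-fold, Cd93 39.4-fold and Flt1 39.6-fold. Of 7 venous genes, 6 were at least 2-fold higher (median 5.14), among them Ackr1 (133-fold, 131 to 136), Selp (52.2-fold), Lrg1 (35.3-fold) and Sele (23.3-fold). Ephb4, a venous receptor, went the other way at 0.574 against 19.0 CPM. Of 11 capillary genes, 8 were at least 4-fold higher (median 5.05), with Fabp4 45.6-fold and Aqp1 33.2-fold higher. Of 9 arterial genes, 6 were at least 2-fold higher (median 1.98). Interferon genes were higher in 8 of 10 cases (median 4.48), and Irf7 went the other way, with 1 count in the double-negative library. Alveolar luminal genes were at least 2-fold higher in 9 of 11 cases (median 2.88, or 3.04 with members at their bound), among them Cd14 (51.3-fold) and Kit (14.7-fold).

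Trp63 stood at 34.1 CPM in the double-negative and 1753 in the PDPN+ library, a ratio of 51.4 (49.1 to 54.0). Krt14 was 11.6-fold lower in the double-negative library (11.3 to 11.9), Krt17 34.3-fold and Lama3 682-fold. Of 12 myoepithelial genes, 11 were at least 2-fold lower (median -4.62), among them Acta2 (21.6-fold), Tpm2 (12.2-fold) and Myh11 (18.7-fold). Of 11 junction genes, 7 were at least 4-fold lower (median -2.54, or -2.73 with members at their bound), with Cdh1 5.81-fold lower, at 37.0 against 215 CPM. Dsg2, a desmosomal cadherin, was 3.65-fold higher in the double-negative library. Of 11 stem cell genes, 6 were at least 4-fold lower (median -2.75), with Sox9 15.2-fold and Id4 51.7-fold lower, while Zeb1 was 213-fold higher (179 to 254). Of 14 Wnt genes, 8 were at least 2-fold lower and 2 higher (median -2.25). Of 9 ID and E protein genes, 3 were at least 2-fold higher, namely Tcf4, Id1 and Tal1, and 2 lower, Id4 and Twist2 (median -0.05, positive under upper quartile scaling). Tcf12 stood at 117 against 121 CPM, Id2 at 39.3 against 55.2 CPM while Tcf3 was 1.98-fold higher. Id1 stood at 27.5 CPM against 0 counts, a ratio of at least 678.

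The largest ratios towards the double-negative library were those of Tgtp2, Mctp1, St3gal6, Gbp2b, Gbp3, Cytl1, Rtp4, Egfl7, Gpm6a and Asb4. Cytl1 and Gpm6a had 0 counts in the PDPN+ library, with ratios of at least 4532 and 3416. Among the largest ratios towards the PDPN+ library were those of Smim3, Elovl4, Pappa, Serpinf1, Tfap2c, Rab39b, Arfip1, Maob and Lin52. Smim3 stood at 184 CPM in the PDPN+ library against 0 counts, a ratio of at least 3104. Serpinf1, Rab39b, Arfip1, Maob and Lin52 also had 0 counts in the double-negative library, with ratios of at least 1225, 1160.8, 1108, 1083 and 1055. The CD36+ library held Smim3, Arfip1 and Lin52 at 44.7, 7.89 and 26.8 CPM, but 2 counts of Maob and 0 of Serpinf1 and Rab39b. The fatty acid elongase Elovl4 and the protease Pappa had 3 counts there, against 359 and 295 CPM. Tfap2c, a transcription factor of epithelial cells, had 2 counts against 154 CPM.

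Of the remaining lists, 9 of 12 fibroblast genes were at least 4-fold lower in the double-negative library (median -3.35). Of 10 Notch genes, 2 were at least 2-fold higher and 5 lower (median -1.02), and of 17 BMP and TGF-beta genes 5 were higher and 4 lower (median 0.42, or 0.00 with members at their bound). Fatty acid genes were higher in 7 and lower in 4 of 13 cases (median 1.34), basement membrane genes higher in 4 and lower in 2 of 12 (median 0.80), and dissociation stress genes higher in 7 and lower in 1 of 15 (median 0.54). Luminal genes were higher in 3 and lower in 4 of 11 cases (median -0.50, or -0.24 with members at their bound), and cell cycle genes higher in 3 and lower in 4 of 10 (median 0.34, or 0.03). Mesenchymal transition genes were higher in 4 and lower in 5 of 10 cases (median -0.25, positive under upper quartile scaling). These differences, too, have no replicate check.

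The CD36+ and double-negative populations share the PDPN-negative sort and the Cdh5 state of the titles and differ in CD36. Endothelial genes were high in both: of 20 pan-endothelial genes, 15 were within 2-fold and 5 at least 2-fold higher in the CD36+ library (median 0.57). Genes of fatty acid handling were higher in the CD36+ library, with 10 of 13 at least 2-fold higher and 0 lower (median 1.32, above 99.9% of random lists). Few abundant genes were far apart, and most of those were higher in the double-negative library. At the size rule, 1097 genes were higher and 1070 lower in the CD36+ library, of 8968. With a mean of at least 160 CPM, 1 gene was higher and 10 were lower, of 1296. Total counts moved the log2 ratios of this pair by -0.17 and turned the balance at the size rule, with 898 higher and 1154 lower.

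Of the fatty acid genes, Fabp4 stood at 5286 CPM in the CD36+ library and 2119 in the double-negative library, a ratio of 2.49 (2.48 to 2.51). Angptl4, an inhibitor of lipoprotein lipase, was 1.88-fold higher, and Gpihbp1, which anchors lipoprotein lipase on capillary endothelium, was 5.20-fold higher (4.90 to 5.53). Scarb1, a lipoprotein receptor, was 3.46-fold higher (3.28 to 3.65). Of 11 capillary genes, 6 were at least 2-fold higher and 0 lower (median 1.03). Aqp1 was 2.04-fold higher and Cdh13 1.61-fold higher, and Car4, a carbonic anhydrase of capillaries, stood at 50.5 CPM against 0 counts, at least 849-fold higher. Fabp4 and Gpihbp1 belong to both lists. Venous genes were within 2-fold in 6 of 7 cases (median 0.13, and -0.05 under total counts), with Selp 1.76-fold higher and Ackr1 1.09-fold higher, and Ephb4 32.9-fold higher in the CD36+ library. Of 12 basement membrane genes, 5 were at least 2-fold higher and 1 lower (median 0.84). Of 15 dissociation stress genes, 7 were at least 2-fold higher in the CD36+ library and 0 lower (median 0.85), among them Ier2 (3.13-fold).

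The 11 genes apart among those with a mean of at least 160 CPM were named after their values were seen. Higher in the double-negative library were Glycam1, a mucin-like ligand of L-selectin that is also made in the lactating gland, at 3021 against 12.5 CPM (242-fold, 225 to 260.1), the lymphoid chemokine Ccl21a, at 3463 against 34.4 CPM (101-fold, 96.5 to 105), and Enpp2, which makes lysophosphatidic acid, at 2889 against 62.3 CPM (46.4-fold, 44.9 to 47.9). Ubd, Serpina1b and Cd74, the invariant chain of MHC class II, were 76.8-fold, 30.5-fold and 15.1-fold higher there. Serpinb1a, Serpinb9 and Tfpi, an inhibitor of coagulation, were 6.83-fold, 5.14-fold and 4.73-fold higher. Dclk1 stood at 510.3 CPM in the double-negative library, 0.236 in the CD36+ library and 456 in the PDPN+ library. Dgkh, a diacylglycerol kinase, was 4.67-fold higher in the CD36+ library (4.49 to 4.85).

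The largest ratios towards the double-negative library were those of Gcnt1, Nxph1, Cxcl13, Pcdhb9, Chst4, Dclk1, Gulp1, Ccdc90b, Ttc33 and Fut7. Gcnt1, Chst4 and Fut7, which build selectin ligands on glycoproteins, stood at 244, 94.5 and 49.1 CPM, against 3, 1 and 0 counts in the CD36+ library. Cxcl13 stood at 181 CPM against 3 counts. Nxph1, Pcdhb9, Gulp1, Ccdc90b and Ttc33 had 0 counts in the CD36+ library, with ratios of at least 1839, 1325, 1158, 1148 and 1049. The largest ratios towards the CD36+ library were those of Gpr160, Echdc1, Mut, Hbb-bs, Car4, Smim3, Hba-a2, Lnx1, Prnd and Rpp30. Except for Lnx1, with 1 count, these had 0 counts in the double-negative library, while the highest of them, Gpr160, stood at 107 CPM in the CD36+ library. Gpr160, Echdc1, Mut, Smim3, Prnd and Rpp30 were at least 1806-fold, 1325-fold, 981-fold, 752-fold, 651-fold and 629-fold higher there. The PDPN+ library also held Gpr160, Echdc1, Mut, Smim3 and Rpp30, at 9.57, 6.99, 10.7, 184 and 29.4 CPM.

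Basal genes were lower in the CD36+ library in 7 of 12 cases and higher in 4 (median -1.78), with Krt14 at 0.186 against 122.6 CPM, Krt17 at 3.35 against 30.4 CPM and Trp63 at 3 counts against 34.1 CPM. Lama3, Itgb4 and Krt5, another basal keratin, went the other way, 15.9-fold, 19.9-fold and 6.06-fold higher in the CD36+ library. Cdh1 stood at 0.861 against 37.0 CPM. Junction genes as a list were higher in 4 and lower in 2 of 11 cases (median 0.24, or 0.09 with members at their bound). Of 9 ID and E protein genes, 5 were at least 2-fold lower in the CD36+ library and 0 higher (median -1.05). Tcf12, Id2 and Id1 were 2.12-fold, 2.07-fold and 2.88-fold lower, Tcf3 was 59.2-fold lower (38.1 to 97.4) and Id4 stood at 0.118 against 6.79 CPM. Mesenchymal transition genes were lower in 6 and higher in 1 of 10 cases (median -1.76), with Zeb2 4.75-fold lower, Vim and Zeb1 1.15-fold and 1.19-fold lower, and Cdh2 higher. Stem cell genes were higher in 4 and lower in 3 of 11 cases (median -0.25).

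The other lists of this comparison had these medians. Cell cycle genes had a median of 1.13, with 5 of 10 at least 2-fold higher in the CD36+ library and 0 lower, among them Mcm3, at 41.6 against 0.0594 CPM, while Tyms and Pcna were 1.86-fold and 1.52-fold higher. Myoepithelial genes had a median of 0.01 and fibroblast genes of 0.08, and both turned under total counts, the former also under upper quartile scaling. The myoepithelial members Cnn1, Lmod1, Oxtr and Actg2 had at most 8 counts in either library, so they say little about this pair. Luminal genes had a median of 0.50, alveolar genes of 0.27, Notch genes of 0.51, Wnt genes of 0.20, BMP and TGF-beta genes of 0.28, interferon genes of 0.39 and arterial genes of -0.11 (0.00 with members at their bound). Hormone-sensing genes had a median of -6.27 (-5.62 with members at their bound) over 7 members, which turned to 2.82 with only members that reached 10 CPM. Of the members, Esr1 and Prlr were higher in the CD36+ library at 39.1 and 35.6 CPM, and Foxa1, Pgr, Tnfsf11 and Cited1 were lower. In the other comparisons the hormone-sensing medians were -0.81 (-1.68 at the bound) for CD36+ against PDPN+ and -0.25 for double-negative against PDPN+, the latter positive under upper quartile scaling.

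The share of genes at least 4-fold apart depended on the level of the gene. Between the CD36+ and double-negative libraries it was 35.7% of genes with a mean of 10 to 20 CPM and 0.965% of the 622 genes with a mean of 320 CPM or more. Against the PDPN+ library the share was 39.98% and 22.7% for the CD36+ library, and 43.4% and 19.6% for the double-negative library. Between the CD36+ and double-negative libraries, 99 of the genes counted as higher and 136 of those counted as lower had 0 counts in the other library.

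**Figure D3:**
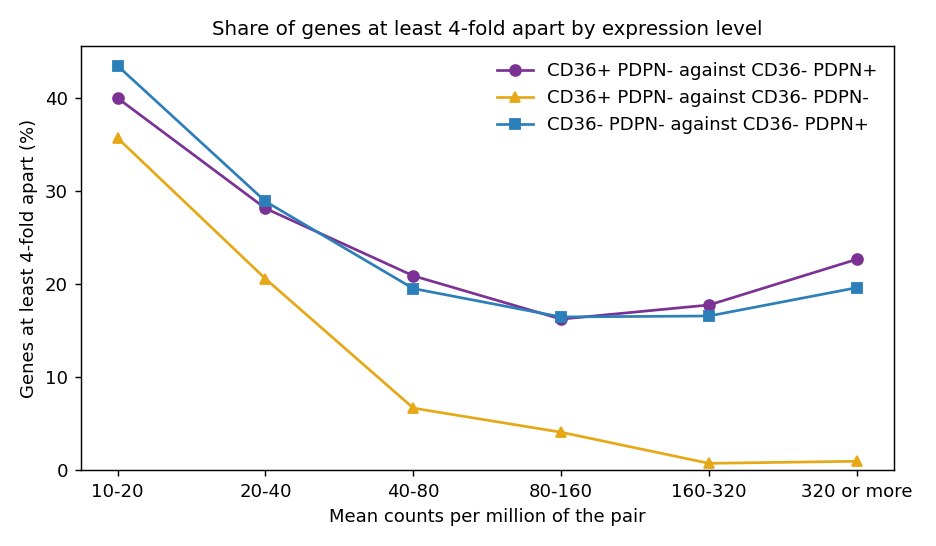
Percent of genes at least 4-fold apart (vertical axis) by the mean CPM of the pair (horizontal axis), with 1 line per comparison. The line of the CD36+ against the double-negative library goes from 35.7% to 0.965%, and the others end at 22.7% and 19.6%.

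Genes at least 4-fold higher in 1 library than in both others numbered 390 for the CD36+ library, 1036 for the PDPN+ library and 424 for the double-negative library. With a mean of at least 160 CPM over the 3 libraries, the numbers were 0, 35 and 8.

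Markers of other cell types that the gate could hold were measured beside these. The summed level of the 7 lymphatic genes was 65.5 CPM in the CD36+ library, 129 in the PDPN+ library and 3506 in the double-negative library, most of the last being Ccl21a. That of the 12 fibroblast genes was 189 CPM, 728 CPM and 139.5 CPM in the same order, with Dcn at 423 CPM in the PDPN+ library. The summed level of the 12 immune genes was 111 CPM in the CD36+ library, 136 in the PDPN+ library and 1009 in the double-negative library, with Cd74 the highest, and the pan-leukocyte gene Ptprc stood at 1.10, 0.798 and 0.9705 CPM. The immune medians were 1.33 (CD36+ against PDPN+), 0.36 (CD36+ against double-negative) and 1.38 (double-negative against PDPN+), over 8 members that went both ways. With only members that reached 10 CPM, the median of CD36+ against PDPN+ turned to -0.28. The lymphatic medians were -1.67, -1.26 (-1.41 with members at their bound) and -0.89 in the same order over 6 members, with Ccl21a highest and Prox1, the lymphatic transcription factor, at 18.1, 6.15 and 21.1 CPM in the CD36+, PDPN+ and double-negative libraries. The pericyte medians were -1.67, 0.58 (0.28 at the bound) and -5.32 (-5.78 at the bound) over 8 members, of which Rgs5 was the most abundant at 241, 51.9 and 164 CPM. With only members that reached 10 CPM, the medians against the PDPN+ library turned to 0.57 for the CD36+ library and 0.51 for the double-negative library. The Schwann medians were -0.83, 0.47 (0.53 at the bound) and -1.93 (-2.05 at the bound) over 4 members, led by Sox10 at 64.6 CPM in the PDPN+ library. Only 2 adipocyte genes were measured, Plin1 and Plin4, both under 10 CPM. Hemoglobin genes were found in the CD36+ library, with Hbb-bs at 51.6 CPM, Hba-a2 at 41.9 and Hba-a1 at 12.9. These 3 genes had 0 counts in the other libraries after rounding, so Hbb-bs was at least 868-fold higher than in the double-negative library. Hba-a2 and Hba-a1 each had a deposited TPM of 0.0338 in the PDPN+ library. The median of these 3 genes was 10.33 against either library, or 10.01 (PDPN+) and 9.46 (double-negative) with members at their bound. RNAs without a poly(A) tail had medians of 0.83, 0.56 and 1.55 (1.61 at the bound) over 19 members, led by Rn7sk at 43.4, 2.02 and 23.5 CPM. Library kits differ in how far they capture such RNAs, and a kit difference between the PDPN+ library and the others was not excluded. As a list, the 8 sort and title genes had medians of 0.88, 0.12 (negative under total counts) and 0.58.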

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

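The minimum mean level of 160 CPM was chosen only after the results were seen, and the other settings before. Values are given in the order CD36+ against PDPN+, CD36+ against double-negative and double-negative against PDPN+, and library-specific genes in the order CD36+, PDPN+, double-negative. Unless said otherwise, the cause of a move was not tested.

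With a 2-fold threshold, 2375 genes were higher and 2633 lower, then 2057 and 1882, then 2419 and 2870, and 969, 1809 and 961 genes were library-specific. With an 8-fold threshold 238 genes were specific to the CD36+ library and 262 to the double-negative library. These follow from the threshold itself.

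Without a minimum level, 3576 genes were higher and 5009 lower, then 3683 and 3774, then 3700.0 and 5208, with 1692, 3225 and 1821 library-specific genes. Pearson correlations were then 0.804, 0.836 and 0.793, and Spearman correlations 0.735, 0.744 and 0.7098. With a minimum of 50 CPM the numbers were 626 and 445, 143 and 158, and 534 and 481, with 47, 297 and 64 library-specific genes. Pearson correlations were 0.253, 0.696 and 0.287, and Spearman correlations 0.437, 0.795 and 0.457. With a mean of at least 160 CPM they were 192 and 62, 1 and 10, and 155 and 63, with 0, 35 and 8 library-specific genes.

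With a prior count of 0.5, Pearson correlations were 0.39003, 0.578 and 0.362, the erythroid median was 12.32 in both comparisons that had it, and the hormone-sensing median between the CD36+ and double-negative libraries was -8.26. With a prior count of 10, Pearson correlations were 0.464, 0.651 and 0.441 and the erythroid median was 8.01 in both. The prior count enters every log2 value and weighs most where a library has few or no counts.

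With the deposited TPM and a pseudocount of 1, Pearson correlations were 0.544, 0.731 and 0.523 and Spearman correlations 0.555, 0.7304 and 0.543. Pan-endothelial medians were 4.51, 0.37 and 4.33, erythroid medians 6.95 and 6.99 against the PDPN+ and double-negative libraries, the stress median of CD36+ against PDPN+ was 1.13 and the fatty acid median of CD36+ against double-negative was 0.99. With a pseudocount of 0.1, the Pearson correlation of CD36+ and double-negative was 0.633, Spearman correlations were 0.555, 0.7304 and 0.543, pan-endothelial medians 4.90, 0.37 and 4.81, and the stress median of CD36+ against PDPN+ was 1.18.

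With total counts, the stress median of CD36+ against PDPN+ was 1.19, and the pan-endothelial and venous medians of CD36+ against double-negative were 0.40 and -0.047. Without mitochondrial, ribosomal protein and the 50 most abundant genes, the Spearman correlation of CD36+ and double-negative was 0.746.

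With list members of at least 10 CPM only, 4 medians of at least 1 in size turned direction. The hormone-sensing median of CD36+ against double-negative was 2.82, the immune median of CD36+ against PDPN+ was -0.28, and the pericyte medians were 0.57 for CD36+ and 0.51 for double-negative against PDPN+. These lists gave no steady direction.

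Over all settings, list medians changed sign in 38 cases, 34 of them medians below 1 in size in the main setting. Of these 38, 10 came with TPM and a pseudocount of 1, 8 with TPM and a pseudocount of 0.1, 9 with list members of at least 10 CPM, 4 with total counts and 4 with upper quartile scaling. Apart from the 4 larger medians that turned, 834 values lay within the bootstrap interval of the main value, sign changes of small medians included, and 19 lay outside it. Of the log2 ratios of named genes, 491 lay within the 95% counting interval of the main value and 262 outside it. Most of those outside came with TPM, 82 with a pseudocount of 1 and 75 with 0.1, or with a prior count of 10, 62. Only 2, 9 and 22 log2 ratios lay within the interval under these settings, in the same order. Counts of genes apart were within 1.5 times the main count in 66 cases and beyond in 24, and library-specific counts in 31 and 14. A count within 1.5 times does not mean that the balance of higher and lower genes held, since it turned under total counts or upper quartile scaling in each comparison. The smallest library had 51138993 counts, and genes of low level in it limit what can be compared. With 1 library per group, leaving a library out was not possible.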

Other observations

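The tests of a basal majority, of Epcam and of milk genes, and the gene lists of this part except for the 6 genes of high endothelial venules, were chosen after at least part of the values had been seen. The low-input test was written after genes without counts had been noticed in the lists, before any share by level was computed. Both PDPN-negative libraries held high levels of inflammatory mediator genes. Dissociation stress genes were also higher there than in the PDPN+ library, with a median log2 ratio of 1.60 and 11 of 15 at least 2-fold higher in the CD36+ library, and 0.54 and 7 of 15 in the double-negative library, so an effect of tissue digestion on these genes was not excluded. Csf3, the granulocyte colony-stimulating factor, stood at 8621 CPM in the CD36+ library, 4493 in the double-negative library and 116 in the PDPN+ library. Il6 was 28.3-fold higher in the CD36+ than in the PDPN+ library and 19.3-fold higher in the double-negative library. Cxcl9, an interferon-induced chemokine, was 186-fold and 111-fold higher, and Nfkbia, a target of NF-kappa B, 15.9-fold and 13.9-fold higher. Of 12 such genes, 8 were at least 4-fold higher in the CD36+ than in the PDPN+ library and 8 in the double-negative library, while Ccl7 was highest in the PDPN+ library, at 328 against 78.0 and 43.9 CPM, and Csf1 was 5.59-fold lower in the double-negative than in the PDPN+ library.

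Genes of antigen presentation were higher in 1 or both PDPN-negative libraries. Of 6 MHC class I pathway genes, 4 were at least 4-fold higher in the CD36+ than in the PDPN+ library (median log2 ratio 3.02) and 3 in the double-negative than in the PDPN+ library (median 2.22). Among them were B2m (6.31-fold and 6.75-fold) and the immunoproteasome gene Psmb8 (14.3-fold and 17.0-fold). The class I median of CD36+ over double-negative was -0.17, and Tap1 was highest in the CD36+ library, at 33.9 CPM against 3.23 in the PDPN+ library and 1.35 in the double-negative library. Of 5 MHC class II genes, 4 were at least 4-fold higher in the double-negative than in the CD36+ library (median of CD36+ over double-negative -2.66), and 4 were at least 4-fold higher in the double-negative than in the PDPN+ library (median 2.48). Against the CD36+ library these were Cd74 (15.1-fold), H2-Aa (6.83-fold), H2-Ab1 (6.34-fold) and H2-Eb1 (6.35-fold), and the class II transactivator Ciita was 2.31-fold higher. The class II median of CD36+ over PDPN+ was -0.28.

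Endothelial genes were among the highest of both PDPN-negative libraries, although the labels give a gate for EpCAM, an epithelial protein. A minority of endothelial cells among basal cells like those of the PDPN+ library would leave basal and junction genes near the PDPN+ level, but over 23 such genes the median log2 ratio was -4.15 (bootstrap interval -7.38 to -2.49) in the CD36+ library and -3.30 (-4.00 to -1.93) in the double-negative library. Endothelial cells as the main part of these sorts, or epithelial cells that carry endothelial transcripts, cannot be told apart, since Epcam mRNA was neither absent nor close to the PDPN+ level, at 9.06% of it in the CD36+ library and 18.5% in the double-negative library. Bulk RNA does not show whether Epcam and Pecam1 were in the same cells, and whether the gate in the labels was applied alike to all 3 sorts was not tested, which keeps this open.

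Most genes apart between the CD36+ and double-negative libraries were of low level. A candidate explanation is that few RNA molecules stood behind the reads of low-input libraries, so that genes of low level were caught or missed by chance. Before the shares were computed it was written that the share of genes apart would be at least 5 times as large at 10 to 20 CPM as at 320 CPM or more, and the ratio was 37.0. Real differences concentrated in genes of low level would give the same, and without a replicate or the kit of each library this stays open.

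Ccl21a and Glycam1 were far higher in the double-negative than in the CD36+ library. Glycam1 is also a milk protein gene, but 5 milk genes had a median log2 ratio of -0.93 (double-negative over CD36+). This argues against milk-secreting cells as the source of the gap, although Wfdc18 and Csn1s1 were 1.61-fold and 1.05-fold higher in the double-negative library. The test does not show that such cells were absent. Against the PDPN+ library the milk genes had a median of 4.69 in the double-negative library, with 5 at least 4-fold higher. As a hypothesis, the double-negative library may hold endothelium of high endothelial venules, the lymphocyte entry vessels of lymph nodes. A test of 6 other genes of these venules was written after Ccl21a and Glycam1 were seen but before the values of the 6 were. It asked for at least 4 of the 6 to be at least 4-fold higher in the double-negative library, and 4 were (Chst4, Fut7, Gcnt1 and Enpp2). Chst2 was 1.09-fold higher in the CD36+ library, a log2 ratio of 0.125 that the shift of -0.17 under total counts would turn. Madcam1 stood at 6.15 CPM in the CD36+ library against 2 counts in the double-negative library. Whether the venule transcripts of the double-negative library come from a population of the gland or from tissue near a lymph node was not tested.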
